A study of Homo sapiens with 6 samples.

How the data were processed

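Poly-A RNA of OVCAR3 cells at passages 20 to 25 was made into libraries with a stranded mRNA kit and sequenced, 3 libraries per vector, per the labels' protocols. The labels say that transfection was done in triplicate but not whether the cultures were otherwise separate, so p-values measure only the spread between these libraries, which may be partly technical. The extraction protocol in the labels names adipocytes as the source of the RNA, while every other label names OVCAR3, and adipocyte markers were therefore measured.

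The authors deposited an expression table in FPKM per gene and library, and a table of their own comparison between the groups. Trimmomatic 0.32, TopHat2 2.1.1, Bowtie, DESeq2 1.12.4 and R 3.3.1 are named, without roles, per the submitters' processing notes. The same notes name the genome builds GRCh38.p5 and hg19 without saying which was used for what. Of the gene identifiers in the deposited tables, 25344 had the same version in GENCODE release 29, and all 25344 had the same coordinates there, so positions are given in GRCh38. The counting tool, the annotation, the filters and whether counting used the strand are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, as are genes with near-identical copies. The authors' comparison table, per the file headers, holds a mean normalised count over the 6 libraries (a signal that is never negative), a log2 fold change with its standard error, a test statistic (a score) and a p-value with its adjusted p-value. The column names are those that DESeq2 writes, per the file headers. The authors' deposited log2 fold change was empty vector over DAB2IP O/E, as found from the FPKM. For the 8277 genes with a mean normalised count over 500, it lay within 0.0113 of the log2 ratio of group means in that direction. The sign was turned for comparison with the values computed here. An adjusted p-value was given for 20272 of 27104 genes in the deposited table and missing for 6832.

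FPKM are not read counts, but the depth could be recovered. The FPKM of a gene, times the authors' deposited mean normalised count and divided by the gene's mean FPKM, were whole multiples of a single step per library, within 0.001 of a whole number for 100% of values in each library. The whole reads recovered per library ran from 20445867 to 35434533. No pair of libraries was a duplicate. Within groups the chi-square per degree of freedom between libraries was 3.61 to 13.2, and between groups it was 16.4 to 28.4.

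The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend, 2-sided) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 6 libraries, with the vector as the term and no covariate. P-values were adjusted by Benjamini-Hochberg over the 14761 genes tested, with a threshold of 0.05. The 12343 genes below the filter were described by level only. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Means, SDs and folds of FPKM are given without the pseudocount. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 of 38 lists with at least 5 members tested, and with camera at an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and compares them with no other genes. With the preset correlation 5 lists passed. With an estimated correlation 0 passed after adjustment and 3 had an unadjusted p under 0.05, and with fry 11 passed. Single values were compared by an exact permutation test, which cannot go below 0.1 with 3 libraries against 3.

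The test, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took DAB2IP, the 12 protein-coding genes with the largest rises and the 12 with the largest falls among those past the threshold and separated between the groups, and up to 4 members of each list with the lowest adjusted p. WNT5B, ALDH1A1, EZH2, CD44, PROM1 and MYC were added whatever their result, and the text prints those of these genes that show each group best. The lists were written from textbook knowledge and comprised Ras GTPase-activating, Ras and MAPK response, WNT ligand, non-canonical WNT, canonical WNT target, ovarian cancer stem cell, PRC2, mesenchymal, epithelial, NF-kB, JAK/STAT3, interferon, antigen presentation, G1/S, G2 and mitosis, p53, apoptosis, unfolded protein, heat shock, hypoxia, cholesterol, fatty acid, YAP, TGF-beta and BMP, NOTCH, integrin and laminin, metalloprotease, transporter, ovarian lineage, growth factor receptor, histone, mitochondrial, ribosomal and oxidative phosphorylation genes. Markers of adipocytes, fibroblasts, leukocytes and endothelial cells made up the remaining lists.

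Alternatives fixed beforehand were other pseudocounts (0.1 and 0.5), no filter or a filter of 5 FPKM, upper-quartile scaling, equal library medians, limma without a trend or with a robust trend, a replicate block, protein-coding genes alone, and each library left out in turn. Alternatives chosen after the data were seen were limma-voom on the recovered reads of genes with a mean of at least 10 reads, limma on log2 recovered normalised counts, and the removal of each library's trends with GC content and gene length by splines with 5 degrees of freedom. GC content was known for 14728 tested genes (99.8%), from the longest transcript in GENCODE 29. Trends with GC content differed between libraries, with Spearman correlations across genes from −0.41 in the second empty vector library to 0.59 in the first library labelled DAB2IP O/E. Chromosome regions were windows of 10 Mb with at least 15 tested genes, of any annotated type, of at least 3 FPKM, compared with 1000 permuted gene orders. Exon overlaps and similarly named pseudogenes were read from GENCODE 29 and the deposited gene names.

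The computations were tested on simulated data, with reads drawn for the real genes at the libraries' depths and 200 genes changed by known folds. For the comparison of DAB2IP O/E with empty vector over 14759 genes tested, the test recovered 12% of genes changed 1.25-fold, 63.3% at 1.5-fold, 98% at 2-fold and 94% at 4-fold. It called 7 of 14560 unchanged genes. The fitted log2 changes were 0.82 to 0.87 of the true ones in the median. Limma-voom over 19047 genes tested recovered 46%, 80%, 100% and 98.0%, and called 5 of 18848 unchanged genes. Each gene was drawn independently, without trends with GC content or length, shifts of chromosome regions or correlation between genes. The share of changed genes was also smaller than the 18.5% called in the data. These rates describe that simpler setting and may not hold for the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.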

Results

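RNA was sequenced from OVCAR3, an established human ovarian cancer cell line, after transfection with an empty vector or with a vector made to overexpress DAB2IP. DAB2IP encodes a scaffold protein with a Ras GTPase-activating domain. There were 3 libraries labelled empty vector and 3 labelled DAB2IP O/E, where O/E stands for overexpression. The comparison asked which transcripts differed in abundance between the cells given these vectors. Expression was given as FPKM for 27104 genes, of which 14761 had a mean of at least 1 FPKM and were tested, 11291 of them protein-coding. Whole reads recovered from the FPKM numbered 20445867, 21967550 and 28116259 in the empty vector libraries. They numbered 35434533, 28738421 and 24743563 in the libraries labelled DAB2IP O/E.

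DAB2IP itself went against the labels. It was at 7.75 ± 0.26 FPKM (SD, n = 3) in the empty vector libraries and at 5.50 ± 0.42 FPKM (SD, n = 3) in the libraries labelled DAB2IP O/E. The gene (ENSG00000136848.16) lies on the plus strand of chromosome 9, from 121567057 to 121785530 in GRCh38. The empty vector libraries had 7.49, 7.76 and 8.01 FPKM, and the libraries labelled DAB2IP O/E had 5.74, 5.02 and 5.73 FPKM, so all 3 values of one group lay below all 3 of the other. Each value rested on 1214 to 1910 reads. The log2 change was −0.43 (SE 0.06), with an adjusted p of 0.00548 (limma, Benjamini-Hochberg). The 2-sided exact permutation test gave p = 0.1, the smallest that 20 assignments of 3 and 3 libraries allow. In the authors' deposited table DAB2IP was likewise higher with empty vector, by a log2 fold change of 0.50 and an adjusted p of 7.27e-09. Every direction given here for the libraries labelled DAB2IP O/E is therefore a direction in libraries with lower, not higher, measured FPKM of DAB2IP.

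In the libraries labelled DAB2IP O/E, which had the lower DAB2IP level, CA2, LRRN1 and GJA1 were among the genes with the largest rises, and FLG, TGM2 and SPARC among those with the largest falls. CA2, a cytosolic carbonic anhydrase, rose from 42.4 ± 3.4 to 158 ± 8.1 FPKM (SD, n = 3 per group). LRRN1, a leucine-rich repeat membrane protein, rose from 1.53 ± 0.18 to 9.70 ± 0.43 FPKM, and GJA1, the gap junction protein connexin 43, from 2.00 ± 0.17 to 10.7 ± 1.6 FPKM. FLG, the epidermal protein filaggrin, fell from 25.0 ± 2.0 to 6.34 ± 0.78 FPKM, and TGM2, a transglutaminase, fell from 29.4 ± 4.1 to 8.93 ± 0.84 FPKM. SPARC, a secreted matrix glycoprotein, fell from 7.23 ± 0.48 to 1.55 ± 0.16 FPKM.

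Other genes among the 12 largest protein-coding rises were S100A9, a calcium-binding protein, with a log2 change of 2.32 and ST6GALNAC5, a sialyltransferase, with 1.77. EHF, an epithelial ETS transcription factor, rose from 6.39 ± 0.29 to 24.0 ± 2.5 FPKM. LTBP1, which binds latent TGF-beta, changed by 1.66 on the log2 scale, NOG, which encodes the BMP antagonist noggin, by 1.65, and the stromelysin MMP10 by 1.56. ERP27, a protein of the endoplasmic reticulum, changed by 1.55 and FBN2, a fibrillin of the matrix, by 1.40. FABP5, a fatty acid-binding protein, changed by 1.45, but reads may be shared with FABP5P1 and FABP5P7, which were also among the genes tested. Among the 12 largest falls were PI3, the elastase inhibitor elafin, with a log2 change of −1.54 and ID4, an inhibitor of DNA-binding transcription factors, with −1.48. TFPI2, a serine protease inhibitor, fell from 76.7 ± 2.5 to 32.4 ± 2.4 FPKM. LOXL4, a lysyl oxidase, changed by −1.15, the cytidine deaminase CDA by −1.09, the G protein subunit GNG11 by −1.08 and the caveolar protein CAV1 by −1.04. RAB31, a small GTPase of vesicle transport, changed by −1.02 and lies within the first 10 Mb of chromosome 18, where the median gene changed by −0.32. TUBA8, an alpha tubulin, changed by −1.01, and 37.0% of its exon bases are shared with PEX26. These 24 genes had adjusted p-values between 6.68e-05 and 0.00954 (limma, Benjamini-Hochberg), and in each the 3 values of one group lay beyond all 3 of the other.

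**Figure D1:**
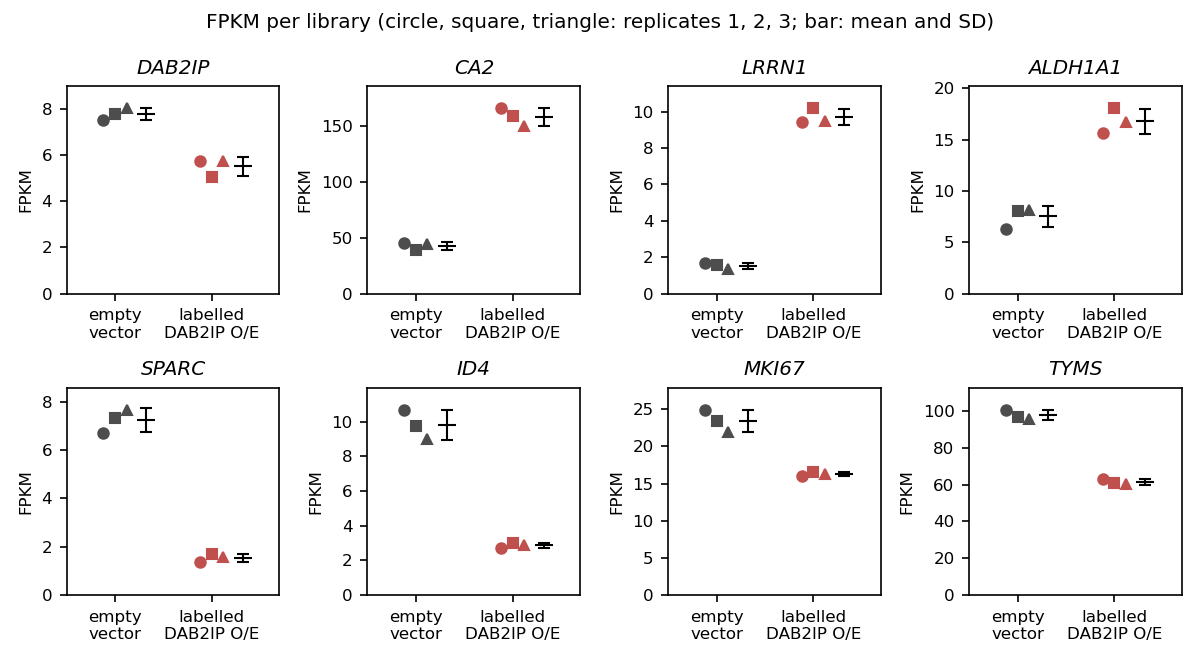
FPKM (vertical axes, starting at 0) of 8 genes in each of the 6 libraries, with empty vector in grey and labelled DAB2IP O/E in red. Circles, squares and triangles are replicates 1, 2 and 3, and the bars give the mean and SD of 3 libraries. DAB2IP, SPARC, ID4, MKI67 and TYMS were lower in all 3 libraries labelled DAB2IP O/E than in any empty vector library, and CA2, LRRN1 and ALDH1A1 were higher.

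Across all genes, 2725 of 14761 (18.5%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1371 higher and 1354 lower in the libraries labelled DAB2IP O/E. With library medians set equal, 1160 were higher and 1673 lower. The median absolute log2 change of these genes was 0.33, and 63 changed at least 2-fold, 41 upward and 22 downward. This last count was 158 and 105 with pseudocounts of 0.1 and 0.5, 34 with a filter of 5 FPKM, 189 on log2 normalised counts and 577 with limma-voom on the recovered reads. Among protein-coding genes, 1152 were higher and 1099 lower. The 3 values of one group lay beyond all 3 of the other in 5970 genes (40.4%). By chance the share is 10% on average over the possible splits. Genes are correlated, so the share in a single split can lie far from that average. The count fell to 956 without the third library labelled DAB2IP O/E, to 1210 without the second empty vector library and to 1289 without the first library labelled DAB2IP O/E. It rose to 4437 with limma-voom on the recovered reads, which tested 19022 genes.

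Many cell cycle genes fell in the libraries labelled DAB2IP O/E, which had the lower DAB2IP level. Of 38 genes of G2 and mitosis, 32 fell and 6 did not pass, 36 fell when adjusted over the list alone, and the median log2 change was −0.26. MKI67, the proliferation marker Ki-67, fell from 23.5 ± 1.5 to 16.3 ± 0.26 FPKM (SD, n = 3 per group). NUSAP1, a spindle-associated protein, fell from 68.4 ± 1.3 to 51.8 ± 0.80 FPKM, and HMMR, the hyaluronan-mediated motility receptor, from 34.9 ± 0.71 to 26.7 ± 1.3 FPKM. NDC80, a kinetochore protein, fell from 37.8 ± 1.6 to 26.5 ± 0.76 FPKM. Of 37 genes of the G1/S transition and S phase, 16 fell and 21 did not pass, 20 fell when adjusted over the list alone, and the median log2 change was −0.18. TYMS, thymidylate synthase, fell from 97.8 ± 2.6 to 61.4 ± 1.6 FPKM, although 39.1% of its exon bases overlap the opposite-strand gene ENOSF1. TYMS and NDC80 both lie within the first 10 Mb of chromosome 18, where the median gene changed by −0.32. The cyclin CCNE1 changed by −0.35 and the replication initiation factor CDC45 by −0.38. Their adjusted p-values were 0.00448 and 0.00619 (limma, Benjamini-Hochberg). Both lists stood apart from the other genes in the camera test of limma with a preset correlation of 0.01, with Benjamini-Hochberg adjusted p-values of 3.92e-15 for G2 and mitosis and 8.23e-08 for G1/S. Neither call held with an estimated correlation, where the adjusted p was 0.332 and 0.0797 (camera in limma, Benjamini-Hochberg).

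Epithelial genes leaned upward in the libraries labelled DAB2IP O/E, with 11 of 25 higher, 1 lower and 13 not passing, 12 higher and 2 lower when adjusted over the list alone. The simple-epithelium keratins KRT18 and KRT8 rose from 244 ± 14 to 398 ± 2.9 FPKM and from 141 ± 8.0 to 226 ± 13 FPKM (SD, n = 3 per group). KRT19 rose from 143 ± 7.0 to 193 ± 13 FPKM, and SPINT1, a serine protease inhibitor of epithelia, from 48.8 ± 0.98 to 61.6 ± 2.4 FPKM. KRT18 and KRT8 overlap each other on opposite strands and have 11 and 10 similarly named pseudogenes among the genes tested, so their reads may be divided. The list's median log2 change was 0.14 and its camera adjusted p was 0.00685 with the preset correlation, against an adjusted p of 0.332 with an estimated correlation (limma, Benjamini-Hochberg). Cytosolic ribosomal protein genes had a median log2 change of 0.10, with 5 of 57 higher, 1 lower and 51 not passing. RPS3 rose from 491 ± 31 to 676 ± 49 FPKM and RPLP2 from 135 ± 6.0 to 166 ± 3.5 FPKM, both in parts of chromosome 11 where the median gene changed by 0.19 and 0.23. Adjusted over the list alone, 2 were higher and 1 lower. The camera adjusted p was 0.00685, against an adjusted p of 0.939 with an estimated correlation (limma, Benjamini-Hochberg). The summed FPKM of the 57 genes was 14100 ± 894 with empty vector and 15169 ± 435 (SD, n = 3 per group) in the libraries labelled DAB2IP O/E (2-sided exact permutation p = 0.2). Without the first empty vector library the ribosomal list had an adjusted p of 0.139, and without the second library labelled DAB2IP O/E it had 0.0640 (camera in limma, Benjamini-Hochberg).

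Subunits of the Polycomb repressive complex PRC2, which methylates lysine 27 of histone H3, were lower in part in the libraries labelled DAB2IP O/E. Of 11 subunits, 4 fell and 7 did not pass, with 6 lower and 1 higher when adjusted over the list alone. The 4 were AEBP2, PHF19, SUZ12 and MTF2, with log2 changes of −0.31, −0.35, −0.24 and −0.24. The catalytic subunit EZH2 was at 12.6 ± 0.48 and 11.0 ± 0.48 FPKM (SD, n = 3 per group), a log2 change of −0.18 with an adjusted p of 0.0507 (limma, Benjamini-Hochberg). The list's camera adjusted p was 0.0357 and its median log2 change −0.14, against an adjusted p of 0.550 with an estimated correlation (limma, Benjamini-Hochberg). Without the third library labelled DAB2IP O/E, none of the 4 genes passed, with adjusted p-values of 0.0573 for AEBP2, 0.105 for PHF19, 0.0927 for SUZ12 and 0.107 for MTF2 (limma, Benjamini-Hochberg). The list itself had an adjusted p of 0.0699 without the first empty vector library and of 0.0658 without the second library labelled DAB2IP O/E (camera in limma, Benjamini-Hochberg). With GC and length trends removed it had an adjusted p of 0.0614 at a median of −0.15 (camera in limma, Benjamini-Hochberg). With a replicate block the list had an adjusted p of 0.0579, and 0.111 with GC and length removal as well (camera in limma, Benjamini-Hochberg).

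Of 12 tested genes used as markers of ovarian cancer stem cells, 3 rose, 1 fell and 8 did not pass, with the same counts when adjusted over the list alone. ALDH1A1, an aldehyde dehydrogenase, rose from 7.51 ± 1.02 to 16.8 ± 1.2 FPKM (SD, n = 3 per group) and lies between 70 and 80 Mb of chromosome 9, where the median gene changed by 0.26. CD24, a surface glycoprotein with the pseudogene CD24P4, rose from 224 ± 4.1 to 317 ± 17 FPKM, and LGR5, a receptor for R-spondins, from 3.48 ± 0.83 to 7.85 ± 0.74 FPKM. NES, the intermediate filament nestin, was at 3.04 ± 0.52 and 2.04 ± 0.19 FPKM, with an adjusted p of 0.0339 (limma, Benjamini-Hochberg) that rose to 0.114 without the third library labelled DAB2IP O/E. The list's camera adjusted p was 0.220 and 0.703 with an estimated correlation (limma, Benjamini-Hochberg). Below the filter on low values, PROM1, which encodes CD133, was at 0.0119 ± 0.0074 FPKM with empty vector and 0.0801 ± 0.0097 FPKM (SD, n = 3 per group) in the libraries labelled DAB2IP O/E. CD44 was at 0.899 ± 0.421 and 0.566 ± 0.049 FPKM. MYC was at 5.62 ± 0.67 and 6.37 ± 0.15 FPKM, with an adjusted p of 0.188 (limma, Benjamini-Hochberg) that became 0.0380 without the first empty vector library.

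Neither list of WNT genes tested with camera passed. Of 9 tested canonical WNT targets, 2 rose, 1 fell and 6 did not pass, 4 higher and 1 lower when adjusted over the list alone, and the camera adjusted p was 0.293 (limma, Benjamini-Hochberg). With fry, which compares the list with no other genes, its adjusted p was 0.0109 (limma, Benjamini-Hochberg). Its risers were LGR5 and the ubiquitin ligase RNF43 at a log2 change of 0.31, and AXIN2, a negative-feedback scaffold that shares 25.2% of its exon bases with AC004805.1, changed by −0.40. The calls of RNF43 and AXIN2 were lost without the third library labelled DAB2IP O/E, with adjusted p-values of 0.115 and 0.0521 (limma, Benjamini-Hochberg). Of 26 genes of non-canonical WNT signalling, 3 rose and 2 fell, both over all genes and adjusted over the list alone, and the camera adjusted p was 0.894 (limma, Benjamini-Hochberg). RYK, a WNT receptor, fell from 55.0 ± 2.5 to 40.4 ± 1.4 FPKM and CAMK2D, a calcium-dependent kinase, rose from 1.30 ± 0.24 to 2.34 ± 0.17 FPKM (SD, n = 3 per group). RYK lies between 130 and 140 Mb of chromosome 3, where the median gene changed by −0.28. The WNT ligands had 3 members tested, too few for a list test, and none passed, with log2 changes of −0.24 for WNT10A, 0.05 for WNT5A and −0.02 for WNT7B and adjusted p-values of 0.206, 0.481 and 0.867 (limma, Benjamini-Hochberg). WNT5B lay below the filter, with 6 reads over the 3 empty vector libraries and 30 over the 3 labelled DAB2IP O/E. The ratio of these rates was 3.91, with an exact 95% counting interval of 1.60 to 11.5. That interval covers counting error alone and no spread between libraries. The authors' deposited table gave WNT5B no adjusted p-value.

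Of 11 Ras GTPase-activating and related genes, 1 rose and 4 fell, both over all genes and adjusted over the list alone, with a camera adjusted p of 0.0915 (limma, Benjamini-Hochberg). IQGAP2, an IQ-motif scaffold with a GAP-related domain, rose from 1.72 ± 0.24 to 4.37 ± 0.21 FPKM (SD, n = 3 per group). Its paralogue IQGAP1 fell from 30.6 ± 0.36 to 23.9 ± 0.63 FPKM, and DAB2IP was a further member that fell. Of 17 Ras and MAPK response genes, 2 rose, 1 fell and 14 did not pass, with the same counts over the list alone and a camera adjusted p of 0.798 (limma, Benjamini-Hochberg). They included the phosphatase DUSP5, with a log2 change of 0.49, and EMP1, an epithelial membrane protein, with −0.47.

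Of 18 genes of the TGF-beta and BMP response, 2 rose, 6 fell and 10 did not pass, both over all genes and adjusted over the list alone. ID2 and ID1, inhibitors of DNA-binding transcription factors, fell from 31.8 ± 1.5 to 15.7 ± 1.0 FPKM and from 61.6 ± 2.25 to 34.4 ± 4.1 FPKM (SD, n = 3 per group). TGFB1, the ligand, changed by −0.44 and LTBP3, which binds latent TGF-beta, by 0.53. LTBP3 lies between 60 and 70 Mb of chromosome 11, where the median gene changed by 0.19. The list's camera adjusted p was 0.0915, and 0.0394 without the second empty vector library (limma, Benjamini-Hochberg). Of 7 tested mesenchymal genes, 1 rose, 2 fell and 4 did not pass, with 1 higher and 3 lower over the list alone and a camera adjusted p of 0.229 (limma, Benjamini-Hochberg). Besides SPARC, the gelatinase MMP2 fell from 5.41 ± 0.45 to 3.11 ± 0.12 FPKM. COL6A1, a collagen VI chain, rose from 2.95 ± 0.28 to 5.08 ± 0.95 FPKM, with an adjusted p of 0.0154 that became 0.0624 without the third library labelled DAB2IP O/E (limma, Benjamini-Hochberg). Among 18 growth factor receptors, 3 rose and 3 fell, with 5 and 4 over the list alone and a camera adjusted p of 0.894 (limma, Benjamini-Hochberg). FGFR2 fell from 21.1 ± 0.23 to 12.5 ± 0.15 FPKM and EGFR from 24.6 ± 2.1 to 16.1 ± 0.56 FPKM, while FGFR1 rose from 7.58 ± 0.91 to 12.7 ± 0.39 FPKM and ERBB2 from 7.49 ± 0.15 to 9.67 ± 0.33 FPKM. Among 17 genes of the ovarian and Müllerian lineage, 1 rose and 6 fell, with 2 and 6 over the list alone. The transcription factors WT1, MECOM and SOX17 changed by −0.45, −0.46 and −0.35, and the kallikrein KLK7 by −0.69. The list's median was 0.04 and its mean −0.05, with a camera adjusted p of 0.758 in the downward direction (limma, Benjamini-Hochberg).

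**Figure D2:**
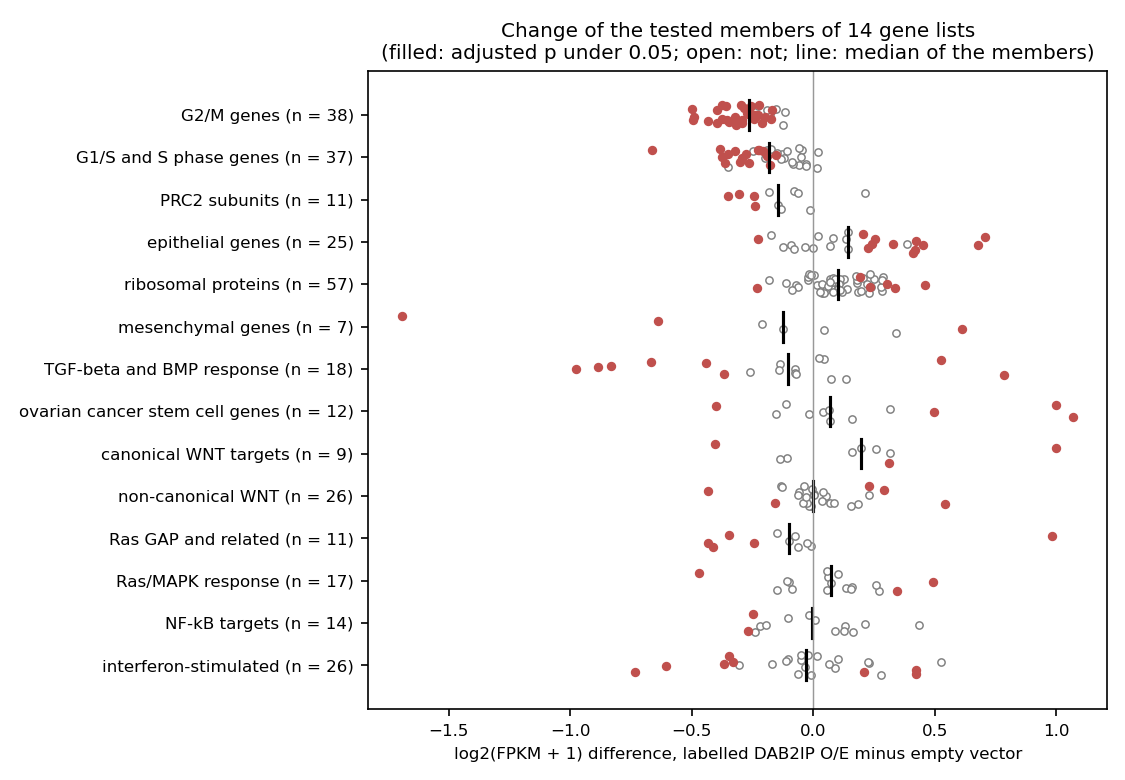
Difference in log2(FPKM + 1), labelled DAB2IP O/E minus empty vector (horizontal axis), of each tested member of 14 gene lists, with filled points for genes at an adjusted p under 0.05 (limma, Benjamini-Hochberg). Black lines mark each list's median, which was −0.26 for the 38 genes of G2 and mitosis and 0.14 for the 25 epithelial genes.

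No other list passed the camera test with the preset correlation. Besides the canonical WNT targets, some lists that did not pass with camera passed with fry, which compares a list with no other genes. Adjusted p-values were 0.00621 for Ras GTPase-activating, 0.0331 for ovarian cancer stem cell and 0.00354 for mesenchymal genes (fry in limma, Benjamini-Hochberg). They were 0.0368 for TGF-beta and BMP, 0.0451 for JAK/STAT3 and 0.00354 for transporter genes (fry in limma, Benjamini-Hochberg). The Ras GTPase-activating list includes DAB2IP itself, and was not tested without it. Among 26 interferon-stimulated genes 3 rose and 5 fell (adjusted p = 0.798, camera in limma, Benjamini-Hochberg), with USP18 changing by −0.61 and HERC5 by −0.73. One of the risers was IRF7, with a log2 change of 0.83 in the authors' deposited table. IRF7 lies in the first 10 Mb of chromosome 11, where the median gene changed by 0.23. Antigen presentation genes gave 1 higher and 2 lower of 15, NF-kB targets 0 higher and 2 lower of 14, and JAK/STAT3 targets 1 higher and 3 lower of 11. OSMR, the oncostatin M receptor, was one of the last and fell from 10.7 ± 1.6 to 6.25 ± 0.22 FPKM (SD, n = 3 per group). The adjusted p-values of these 3 lists were 0.798, 0.894 and 0.259 (camera in limma, Benjamini-Hochberg). Of 28 hypoxia and glycolysis genes none rose and 6 fell, among them ALDOC, an aldolase, at a log2 change of −0.45 and PFKFB3 at −0.31 (adjusted p = 0.154, camera in limma, Benjamini-Hochberg). Of 23 genes of cholesterol synthesis 1 rose and 5 fell, and of 20 genes of fatty acid metabolism 2 rose and 2 fell, with adjusted p-values of 0.102 and 0.894 (camera in limma, Benjamini-Hochberg). SCD, the stearoyl-CoA desaturase, fell from 417 ± 8.9 to 326 ± 6.5 FPKM, and TM7SF2, a sterol reductase, rose from 22.9 ± 1.4 to 34.0 ± 2.1 FPKM. TM7SF2 was the 1 riser of the cholesterol list. Among its 5 fallers, HMGCS1, SQLE and CYP51A1 changed by −0.41, −0.29 and −0.28 in the authors' deposited table. Of 31 genes of the unfolded protein and integrated stress responses 4 rose and 3 fell, with XBP1 at a log2 change of 0.44 and CEBPB at −0.41 (adjusted p = 0.514, camera in limma, Benjamini-Hochberg). YAP targets gave 5 higher and 2 lower of 19. The 2 lower were AMOTL2 at −0.42 and TGFB2, which shares 26.6% of its exon bases with TGFB2-OT1, at −0.46. The risers included ARHGEF17 and NUAK2, at 0.41 and 0.28 in the authors' deposited table. ARHGEF17 lies between 70 and 80 Mb of chromosome 11, where the median gene changed by 0.19. NOTCH genes gave 4 higher and 1 lower of 14, including the ligand JAG1 at 0.29. The adjusted p-values of the YAP and NOTCH lists were 0.894 and 0.428 (camera in limma, Benjamini-Hochberg). The median gene changed by −0.22 around OSMR (30 to 40 Mb of chromosome 5), by −0.28 around AMOTL2 (130 to 140 Mb of chromosome 3) and by 0.19 around TM7SF2 (60 to 70 Mb of chromosome 11).

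Integrin and laminin genes gave 3 higher and 3 lower of 19, with the laminin chain LAMB1 at a log2 change of 0.50. Metalloproteases and their inhibitors gave 3 higher and 2 lower of 13, and ABC and copper transporters 3 higher and 0 lower of 12, with ABCA3 at 0.51 and ABCG1 at 0.49. The adjusted p-values of these 3 lists were 0.894, 0.798 and 0.0915 (camera in limma, Benjamini-Hochberg). Genes regulated by p53 gave 1 higher of 21, apoptosis regulators 1 higher and 2 lower of 21, including BID at −0.37, and heat shock and immediate early genes 1 higher of 21. The adjusted p-values were 0.443, 0.907 and 0.971 (camera in limma, Benjamini-Hochberg). Replication-dependent histones gave 1 higher and 2 lower of 20, with HIST1H2BH at −0.68, although poly-A selection captures few histone transcripts, and nuclear oxidative phosphorylation genes 2 higher and 1 lower of 29. The adjusted p-values were 0.894 and 0.995 (camera in limma, Benjamini-Hochberg). In the heat shock, histone and non-canonical WNT lists the signs of the median, the mean and the camera direction differed. The median was 0.05 with a downward test for heat shock, 0.03 with a downward test for histones and just below 0 with an upward test for non-canonical WNT.

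Markers of other cell types were mostly low, and no sum of them could pass a threshold of 0.05 in this design. The summed FPKM of 14 adipocyte markers was 15.1 ± 0.30 with empty vector and 19.6 ± 1.8 (SD, n = 3 per group) in the libraries labelled DAB2IP O/E (2-sided exact permutation p = 0.1, Benjamini-Hochberg adjusted over 6 sums 0.3). Most of it came from PNPLA2, a triglyceride lipase that changed by 0.43 and lies in the first 10 Mb of chromosome 11, where the median gene changed by 0.23. The 2 adipocyte markers tested, PNPLA2 and DGAT2, were both higher at an adjusted p under 0.05 (limma, Benjamini-Hochberg). DGAT2 lies between 70 and 80 Mb of chromosome 11, where the median gene changed by 0.19. The adipocyte lipid droplet protein PLIN1 was at 0.0159 ± 0.0276 and 0.0206 ± 0.0271 FPKM. Of 11 fibroblast markers, FBLN1 was at 7.82 ± 0.40 and 6.96 ± 0.31 FPKM and S100A4 at 222 ± 20 and 209 ± 6.8 FPKM, and the sum was 232 ± 20 and 218 ± 6.4 FPKM (exact permutation p = 0.3, adjusted 0.36). The sums of 8 leukocyte markers were 2.65 ± 0.27 and 2.00 ± 0.35 FPKM and those of 9 endothelial markers 4.45 ± 0.71 and 5.33 ± 0.53 FPKM, with the macrophage protein CD68 and EGFL7 as the respective members tested (exact permutation p = 0.2 and 0.2, adjusted 0.3 and 0.3). The 13 mitochondrially encoded genes summed to 59071 ± 11216 and 55259 ± 3679 FPKM (exact permutation p = 0.9, adjusted 0.9), and the camera adjusted p of that list was 0.704 (limma, Benjamini-Hochberg). Mitochondrial genes took 4.72% to 6.39% of reads per library, with the highest share in the first empty vector library. The first principal component, with 55.4% of the variance, separated the groups.

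Most genes that changed here were also called in the authors' deposited table. Of the 2725 genes, 2443 had an adjusted p under 0.05 in the authors' deposited table, all of them in the same direction, and 282 did not. The authors' deposited table called 846 further genes among those tested here. The Spearman correlation of the log2 changes with those in the authors' deposited table was 0.994 across genes, which are not independent replicates. Both rest on the same libraries, so the overlap describes the tools and not a second experiment.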

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

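This part uses genes outside the test of the report, and the genes named were chosen after their values were seen, as the 4 largest rises and 4 largest falls among protein-coding genes with a mean normalised count of at least 10. Among the 12343 genes with a mean under 1 FPKM, 561 had an adjusted p under 0.05 in the authors' deposited table, 451 of them protein-coding. They stood out because they lay outside the genes tested here and yet differed between the groups, 340 higher and 221 lower in the libraries labelled DAB2IP O/E, which had the lower DAB2IP level. BMP3, a bone morphogenetic protein, had 0 reads over the 3 empty vector libraries and 82 over the 3 labelled DAB2IP O/E, at least 21.4-fold higher against a floor of 3 reads over the group. COLEC10, a collectin, had 1 and 105 reads, a rate ratio of 82.1 with a 95% counting interval of 14.4 to 3272. TMPRSS15, which encodes enteropeptidase, had 1 and 85 reads (66.4, interval 11.6 to 2655), and S100A7A, of the S100 family, had 1 and 78 reads (61.0, interval 10.6 to 2439). In the other direction, ZIC2, a zinc finger transcription factor, was at 1.33 ± 0.20 FPKM with empty vector and 0.0818 ± 0.0448 FPKM (SD, n = 3 per group) in the libraries labelled DAB2IP O/E, from 314 and 25 reads. Its neighbour ZIC5 on chromosome 13 had 74 and 3 reads, a ratio of 0.0317 (interval 0.00639 to 0.0963). C6orf223 had 149 and 13 reads, and CELF6, an RNA-binding protein, 119 and 22. These intervals cover counting error alone. No technical or biological explanation of these values was tested.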

How the results depend on the processing

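Voom, log2 normalised counts and GC and length removal were chosen after the data were seen, and DESeq2 was listed beforehand but not run, while limma-voom was run on the recovered reads. DAB2IP, the cell cycle lists and the epithelial list kept direction and call in every fit, except that no list passed with an estimated correlation. With each library left out, changed genes ranged from 956 to 2731 (507 to 1424 higher, 449 to 1307 lower), lists passing from 3 to 6, the adjusted p of PRC2 from 0.0325 to 0.0699 and that of ribosomal proteins from 6.02e-05 to 0.139 (camera, Benjamini-Hochberg). Leaving out the third library labelled DAB2IP O/E gave 956 genes, the second empty vector library 1210 and the first labelled DAB2IP O/E 1289, with fewer samples. Of 190 other genes and lists, 9 to 46 lost and 0 to 5 gained a call this way. Voom called 4437 genes (2281 higher, 2156 lower). Genes changed at least 2-fold numbered 158 and 105 with pseudocounts of 0.1 and 0.5, 34 with a filter of 5 FPKM, 189 on log2 normalised counts and 577 with voom, against 63, and the cause was not tested. With equal library medians 40.9% of calls were higher, against 50.3%. With an estimated correlation 0 lists passed, and adjusted p-values were 0.332 (G2 and mitosis), 0.0797 (G1/S), 0.550 (PRC2), 0.332 (epithelial) and 0.939 (ribosomal). Fry passed 11 lists but not ribosomal proteins (0.257). PRC2 had 0.0614 after GC and length removal, where its median was −0.15 against −0.14 before, and the cause of the lost call was not tested. At 0.01 in both, 760 genes were shared with the authors' deposited table. Same-numbered libraries deviated together by correlations of 0.12, 0.10 and 0.06, each sample correlating best with its own number, a hint from the data alone. The replicate block gave 2393 genes, and PRC2 an adjusted p of 0.0579, or 0.111 with GC and length removal. No result reversed where either value passed, a condition set after the first values were seen. Of the smallest simulated changes the test recovered 12% and limma-voom 46%.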

Other observations

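The genes named here beyond the fixed rule, the tests of annotated gene types and, among the tests below, those of DAB2IP, of the permuted gene order, of the GC and length trend in cell cycle genes and of other splits were chosen after the results were seen. The fixed list of the TGF-beta and BMP response did not pass as a group, with a camera adjusted p of 0.0915, or 0.701 with an estimated correlation (limma, Benjamini-Hochberg), so the following are single genes. In the libraries labelled DAB2IP O/E, which had the lower DAB2IP level, NOG, which encodes a BMP antagonist, rose from 0.894 ± 0.344 to 4.89 ± 0.67 FPKM (SD, n = 3 per group), and ID1, ID2 and ID4, which BMP signals induce in many cells, changed by −0.83, −0.98 and −1.48 on the log2 scale. SMAD6 and SMAD7, inhibitory SMADs, changed by −0.67 and −0.89, with adjusted p-values of 0.00494 and 0.00548 (limma, Benjamini-Hochberg). The extracellular protein TNC, in the same list, changed by 0.79.

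Genes annotated as antisense RNA were mostly lower where they changed, with 14 higher and 71 lower of 410 tested, against 1152 higher and 1099 lower of the protein-coding genes (Fisher's exact p = 1.19e-10, 3.58e-10 adjusted by Benjamini-Hochberg over 3 types). EMX2OS fell from 26.7 to 18.3 FPKM and HOXA-AS2 from 9.04 to 6.05 FPKM. Antisense genes held 0.429 ± 0.013% of reads with empty vector and 0.383 ± 0.003% (SD, n = 3 per group) in the libraries labelled DAB2IP O/E, with a 2-sided exact permutation p of 0.1. Processed pseudogenes were mostly higher where they changed, with 136 higher and 60 lower of 1654 tested (Fisher's exact p = 1.02e-06, adjusted 1.52e-06). Intergenic long RNAs gave 26 higher and 40 lower of 327 (Fisher's exact p = 0.0618, adjusted 0.0618). The downward lean was not particular to antisense genes. Sense-intronic genes gave 1 higher and 13 lower of 74, miscellaneous RNAs 1 and 9 of 58, and small nucleolar RNAs 1 and 5 of 137. MicroRNA genes gave 5 higher and 4 lower of 69, and processed transcripts 11 and 13 of 154. These further types were not tested. Genes are not independent replicates, and reads of antisense genes and pseudogenes cannot be told from those of their partners without knowledge of the counting.

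DAB2IP was lower in the libraries labelled DAB2IP O/E, at a ratio of 0.709 to empty vector. A swap of single libraries between the groups was argued against by the values per library, since 0 libraries had a level within the other group's range. A trend with GC content or length was argued against too, since the log2 change was −0.50 (SE 0.04) once such trends were removed. Loss of the surrounding chromosome region would also have lowered the neighbours of DAB2IP. Their median over 36 tested protein-coding genes within 5 Mb was −0.062 (95% interval −0.12 to −0.01). That interval resamples the neighbours, which are not independent replicates, and covers no spread between libraries. A loss of only a few genes would hardly move this median, so a smaller loss was not tested. The neighbour PHF19, from 120855652 to 120894896, changed by −0.52 in the authors' deposited table, where DAB2IP changed by −0.50. An exchange of all 6 labels could give the ratio of 0.709, and so could an introduced sequence that gave few mapped reads while the endogenous gene fell. Under an exchange, DAB2IP would be only 1.41-fold higher in the cells given its vector. These and other explanations, such as a difference between subclones without overexpression, cannot be told apart, because no vector sequence was among the genes measured.

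Neighbouring genes shifted together along chromosomes. In 245 windows of 10 Mb holding 9782 genes, the window medians had an SD of 0.0849, above all 1000 permuted gene orders (highest 0.0472), so that 1 order, the observed one, had as large a spread. Among other splits of the libraries the highest SD was 0.0561, also above every permuted order. In the real split 13 windows lay beyond the permuted limit of 0.185 from the median of all these genes (−0.0054). The lower windows included 0 to 20 Mb of chromosome 18, with medians of −0.32 and −0.30, and 120 to 160 Mb of chromosome 3, with medians from −0.22 to −0.28, and the higher ones included 0 to 10 Mb of chromosome 11 (0.23), 80 to 90 Mb of chromosome 17 (0.25) and 70 to 80 Mb of chromosome 9 (0.26). Of the 13, 9 stayed beyond the limit permuted anew once GC and length trends were removed (0.168 from a median of −0.011), and 7 beyond the first limit, which argues against these trends as the whole source, and the windows at 30 to 40 Mb of chromosome 5, 100 to 110 Mb of chromosome 3 and 60 to 80 Mb of chromosome 11 did not stay. Weakly and strongly expressed genes of a window shifted alike, with a correlation of 0.640 across windows against at most 0.187 in permuted orders. This correlation was computed before GC and length trends were removed, and any cause shared by the genes of a region could give it. A candidate explanation, not tested on DNA, is a different copy number of these regions in the cells of the groups, as between subclones, and other regional causes stay open. The 13 windows held 851 tested genes and 372 of the 2725 changed genes, and 2353 changed genes lay elsewhere. Those 2353 are not shown to be free of regional shifts. Some tested genes lay in no window, and some windows short of the limit leaned too. Examples are 110 to 120 Mb of chromosome 3 (−0.19) and 70 to 80 Mb of chromosome 17 (0.16).

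Of the 75 tested cell cycle genes of both lists, 48 fell in the libraries labelled DAB2IP O/E and 27 did not pass, with a median log2 change of −0.24, although neither list passed with an estimated correlation (adjusted p = 0.332 and 0.0797, camera in limma, Benjamini-Hochberg). Removal of GC and length trends left a median of −0.25 (95% interval −0.27 to −0.21), and subtraction of each region's median left −0.23 (interval −0.26 to −0.20), which argues against both as the whole source. These intervals resample the genes, which are not independent replicates, and cover no spread between libraries. Depth as the whole source was argued against by the third libraries. The one labelled DAB2IP O/E had fewer reads and yet a median of −0.22 below its empty vector counterpart, with 73 of 75 genes lower. That sets 1 library against 1. The first and second libraries labelled DAB2IP O/E were deeper than every empty vector library, so a part played by depth is not excluded. Subtraction of regional medians removes only the shift of each gene's own region, and cannot speak to other differences between subclones. The difference in DAB2IP, an effect of the transfected vector and a difference between subclones stay open, and no biological explanation was tested.

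Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 2725 genes and the highest of the others 0, so 1 of the 10 splits had as many. For lists with the preset correlation the real split called 5 and the highest of the others 7, and 7 of the 10 splits called as many. Both cell cycle lists passed in all 9 other splits, with medians of at most 0.14 and 0.07 in size against 0.26 and 0.18 in the real one, whereas ribosomal proteins passed in 5, with a median of up to 0.12 in size against 0.10 and an adjusted p down to 1.63e-10 against 0.00685 (camera in limma, Benjamini-Hochberg), and the PRC2 and epithelial lists passed in 0. Each other split sets 2 libraries of a group and 1 of the other against the rest and so keeps part of the real contrast. The rest of that contrast adds to the spread within each side of the split. A count of 0 genes was therefore likely beforehand, and nothing is concluded from the gene counts of the other splits.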
